A study of Mus musculus with 4 samples.

How the data were processed

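RNA was measured on 4 one-colour oligonucleotide arrays, each holding 45101 probe sets, of which 64 were control probe sets. Per the labels' protocols, each array held RNA from 1 sorted population, taken from a pool of 20 testes of 2-week-old Sox2GFP mice on a mixed 129SvJae and BL6 background. Testes were dissociated with collagenase, stained with an antibody against ckit and sorted by reporter fluorescence and ckit signal, with dead cells excluded by propidium iodide. Between 20000 and 90000 cells went into a sample, and 5 ng of total RNA was amplified and labelled with biotin. The groups were the Sox2GFP+ckit- and the Sox2GFP+ckit+ population, with 2 biological replicates each according to the labels.

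The deposited value table held log2 expression values, which the authors had made with RMA (background correction, quantile normalization and summary of the probes of a probe set), per the submitters' processing notes. The version of RMA, the array model and the treatment of individual probes were not given in the sources used here. The array medians lay between 6.39 and 6.42 and the quartiles between 4.93 and 8.15, so the arrays had nearly the same distribution and were not normalized again for the comparison. Because quantile normalization makes the distributions alike, a shift of all transcripts between the populations would not be visible in these values.

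A second deposited table held the authors' own comparison of the same 4 arrays: group means and standard errors on the log2 scale, a ratio (linear fold) of the group means, a p-value and an adjusted p-value. Per the file headers, it came from a t-test with Benjamini-Hochberg correction over 605 tests and a 2-fold threshold. It listed 374 probe sets. Its group means were not those of the RMA table: for Sox2GFP+ckit+ cells the authors' deposited table minus the RMA table gave a median of -0.20, with a range of -1.22 to 1.09 on the log2 scale. How the values in that table had been normalized was not given in the sources used here.

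Differences were tested with limma version 3.58.1 in R version 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05) on the deposited log2 values of all 45037 non-control probe sets, with no filter on level. The effect was Sox2GFP+ckit+ minus Sox2GFP+ckit-, over all 4 arrays and without covariates. The ± beside a log2 difference is limma's standard error and the ± beside a group's level is the SD of its 2 arrays. Limma's p-values measure the spread between 2 pools per population. The number of arrays limits the precision: an exact permutation test of 2 arrays against 2 cannot go below p = 0.333, so single probe sets were judged by limma, which pools the spread across probe sets.

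Gene names were taken from the deposited comparison table, the only table used here that pairs probe sets with names. Of its 374 probe sets, 256 were named, covering 220 genes: 61 through a RefSeq accession, 101 through a symbol in the description and 94 through a full gene name matched by hand. The symbols and accessions were matched to a RefSeq gene table of the GRCm38.p6 assembly, from which no coordinates were used, and 118 probe sets of the deposited table stayed unnamed. For the 30 genes with more than 1 named probe set, the one with the highest mean over the 4 arrays stands for the gene. All probe sets of a gene had the same sign in 30 of the 30 genes and the same call in 16. The design set before the data were examined had foreseen 1 probe set per gene and a competitive test (camera) of 24 gene lists over all genes. Neither could be made without names for the other probe sets, so limma was run on every probe set and lists were tested by direction only.

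Each list with at least 5 named genes was tested with a two-sided Fisher's exact test of how many of its named genes were higher in either population, against the other named genes, with Benjamini-Hochberg adjustment over the 2 lists that qualified. All named genes had been selected by the authors on these 4 arrays for a difference of at least 2-fold, with adjusted p-values up to 0.05 in their t-test. The direction of a list among them is therefore not independent evidence, and a list without named genes was not analysed here. Fisher's test also counts genes as independent, though their signs come from the same 4 arrays, so its p does not measure the spread between pools. Apart from the direction tests, the 24 lists served to group the named genes.

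The genes named in the text follow a rule set before the data were examined: Kit and Sox2 with every probe set, then the 10 genes with the highest and the 10 with the lowest log2 difference. These had to have an adjusted p under 0.05, no overlap between the groups' arrays and a mean above the median of all probe sets in the higher group, without RIKEN, Gm, LOC, EST or predicted names. From each list that passed its test or had a member past the threshold, up to 4 members with the smallest p were named, and from a list with none, up to 2, as values only. Sox2 was not among the named genes, and 1 gene that the rule takes is not reported here.

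The code was tested on simulated data in 20 runs over 45037 probe sets, 2 arrays against 2, with 200 changed probe sets in each run. Limma recovered 2.33% of probe sets changed by 1 on the log2 scale, 84.9% of those changed by 2 and 98.1% of those changed by 3. Of the calls, 5.42% were false and 0 had the wrong sign. In simulations without any change, 1 of the 20 runs made a call. Errors were drawn independently for each probe set and array, so limma's rates here leave out what arrays share. They need not hold for these data. The direction test was tried apart from these arrays, on independent random signs for 220 genes and a list larger than those tested. There 3.1% of tests fell under 0.05. Such draws leave out that genes on the same arrays vary together, so they do not show the error rate for these data.

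The alternatives were the replicate number as a block, an intensity trend in eBayes, a filter that kept the 23290 probe sets above the array median on at least 2 arrays, renewed quantile normalization, centring on the array median and leaving out each array in turn. The methods' t-test and an adjustment over the 2-fold probe sets alone were added after the data had been seen. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.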

Results

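The data were gene expression profiles of cells sorted from the testes of 2-week-old mice that carry a green fluorescent protein reporter of Sox2. Reporter-positive cells were separated by surface ckit, the receptor for stem cell factor, into a Sox2GFP+ckit- and a Sox2GFP+ckit+ population (ckit- and ckit+ cells below), each measured on 2 arrays from pools of 20 testes. The question was how the transcripts of these populations differ, the labels describing the material as testis cells able to rebuild damaged tubules. Array values correlated across probe sets with r = 0.987 between the ckit- arrays and 0.989 between the ckit+ arrays, and with 0.980 to 0.984 between arrays of different populations. Probe sets are not independent replicates, so these coefficients only describe the arrays. For the GAPDH control probe sets, the 3′ signal exceeded the 5′ signal by 2.68 and 2.61 on the log2 scale in ckit- arrays and by 2.45 and 2.59 in ckit+ arrays. For beta-actin, 3′ minus 5′ was -0.11 and -0.19 in ckit- arrays and 0.02 and -0.27 in ckit+ arrays.

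Ret, Gfra1, Etv5 and other genes listed for undifferentiated spermatogonia were higher in ckit- cells, while Kit, Stra8, Crabp1 and Rbp4 were higher in ckit+ cells. Ret and Gfra1, the receptor and co-receptor for the niche factor GDNF, were 4.73-fold (log2 difference 2.24 ± 0.17) and 4.54-fold (2.18 ± 0.19) higher in ckit- cells. Stra8, a retinoic acid-induced gene needed for entry into meiosis, was 3.25-fold higher in ckit+ cells (1.70 ± 0.16). Limma called 139 of 45037 probe sets at an adjusted p under 0.05 (n = 2 arrays per group), 87 higher in ckit- and 52 higher in ckit+ cells. All 139 differed by at least 2-fold, the smallest by 1.26 on the log2 scale. Smaller differences could hardly pass in this fit: in the simulations, which drew errors independently, limma recovered 2.33% of probe sets changed by 1. With an intensity trend or the replicate number as a block, some probe sets less than 2-fold apart did pass. Over all probe sets, the arrays of the populations did not overlap in 48.6%, against 33.3% expected by chance for 2 against 2. Without ties, each probe set separates under 1 of the 3 possible splits of 4 arrays, so some split always reaches about 33.3%. Probe sets share these arrays, so the share only describes them.

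**Figure D1:**
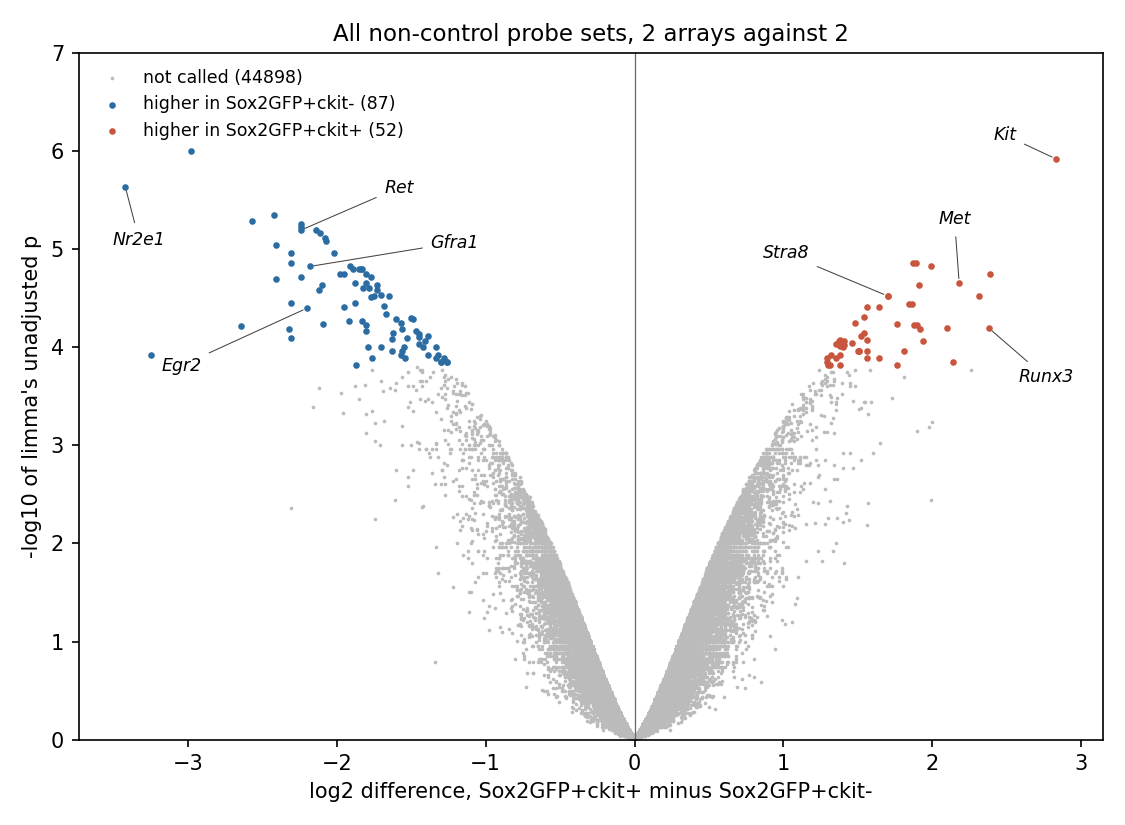
The log2 difference of each of the 45037 non-control probe sets (horizontal axis, Sox2GFP+ckit+ minus Sox2GFP+ckit-) is plotted against -log10 of limma's unadjusted p, each point a probe set tested on 2 arrays per population. The 87 probe sets called higher in ckit- cells lie on the left in blue and the 52 called higher in ckit+ cells on the right in red, with Kit at 2.83 and Ret at -2.24.

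Kit, whose protein product defined the sort, checked the labels. Its brighter probe set had a mean of 9.65 ± 0.04 in ckit+ cells and 6.83 ± 0.06 in ckit- cells (log2, SD, n = 2), a 7.09-fold difference with limma's adjusted p = 0.026. The second Kit probe set was 4.81-fold higher in ckit+ cells (log2 difference 2.26 ± 0.29, limma's adjusted p = 0.052) and did not pass the threshold.

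Of the 39 genes listed for undifferentiated spermatogonia, 13 were named, and 13 of the 13 had higher values in ckit- cells, with a median log2 difference (ckit+ minus ckit-) of -1.73. By limma, 8 of them passed the threshold over all probe sets. Adjusted over the list alone, all 13 passed, as did every named member of each other list, an outcome fixed by the authors' selection of genes that differ on these arrays and no evidence of its own. Besides Ret and Gfra1, Upp1, which encodes uridine phosphorylase, was 4.05-fold higher in ckit- cells (log2 difference 2.02 ± 0.16, limma's adjusted p = 0.027). Etv5, a transcription factor induced by GDNF, was 3.61-fold higher (1.85 ± 0.16, limma's adjusted p = 0.027). The values of Gfra1 are those of its brightest probe set, and the others, 3.62-fold (1.85 ± 0.27) and 2.01-fold apart (1.01 ± 0.16), did not pass (limma's adjusted p = 0.063 and 0.080). Over all 220 named genes, 115 were higher in ckit- and 105 in ckit+ cells, and the list's direction differed from that of the other named genes (Fisher's exact test, two-sided, p = 0.0002, adjusted p = 0.0004). The authors had selected these genes on the same arrays, so the direction is not independent evidence. Fisher's test also counts genes as independent although they share the same arrays, so its p does not measure the spread between pools. The only named endothelial gene, Plvap, and the only named gene of the dissociation response, Egr2, were higher in the same cells, by 2.72-fold (log2 difference 1.45 ± 0.16) and 4.58-fold (2.20 ± 0.22).

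Of 27 genes listed for GDNF and FGF signalling, 6 were named, and each of them also stood in the list of undifferentiated spermatogonia. All 6 had higher values in ckit- cells, with a median log2 difference of -1.68 (Fisher's exact test, two-sided, p = 0.03, adjusted p = 0.03). The limits given above for Fisher's test hold here too. Without dim probe sets 5 named genes were left and the list no longer passed (Fisher's exact test, two-sided, p = 0.059). Limma called 3 over all probe sets (Ret, Gfra1 and Etv5). Sdc4, a heparan sulfate proteoglycan, had means of 12.77 ± 0.05 in ckit- and 11.25 ± 0.41 in ckit+ cells (log2, SD, n = 2) and did not pass over all probe sets (limma's adjusted p = 0.068).

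For differentiating spermatogonia, 4 of 17 listed genes were named and 4 of 4 had higher values in ckit+ cells, too few for the direction test. Kit and Stra8 passed the threshold by limma, but Kit defined the sort, so its direction was set by the design. Stra8 reached a mean of 13.07 ± 0.10 in ckit+ and 11.37 ± 0.06 in ckit- cells (log2, SD, n = 2, limma's adjusted p = 0.028), so its transcript was bright in both. Dnmt3b, a de novo DNA methyltransferase, had a log2 difference of 1.10 ± 0.16 (limma's adjusted p = 0.069). The homeobox gene Rhox13 had a log2 difference of 1.10 ± 0.18 (limma's adjusted p = 0.085).

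Of 24 genes listed for retinoic acid metabolism and signalling, 4 were named, all with higher values in ckit+ cells. By limma 3 passed over all probe sets. Crabp1, a cytoplasmic retinoic acid-binding protein, was 3.38-fold higher in ckit+ cells (log2 difference 1.76 ± 0.19, limma's adjusted p = 0.037). Rbp4, a retinol carrier, was 2.87-fold higher (1.52 ± 0.17, limma's adjusted p = 0.041). Stra8 belonged to this list too.

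**Figure D2:**
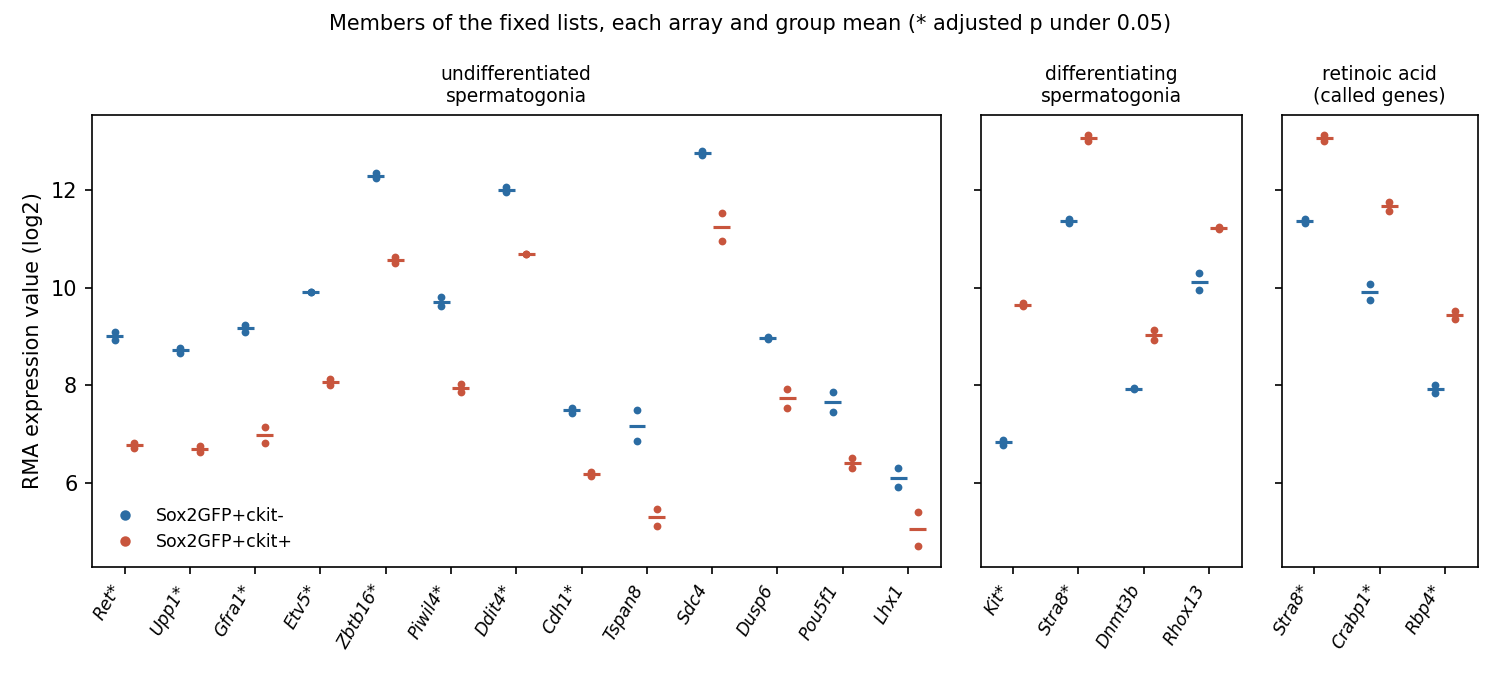
RMA expression values (vertical axis, log2) of the named genes in the lists for undifferentiated and differentiating spermatogonia and of the 3 called genes in the list for retinoic acid, with a point for each array (n = 2 per population), a bar for the mean and an asterisk where limma's adjusted p was under 0.05. The 13 genes on the left lie higher in Sox2GFP+ckit- cells (blue) and the 4 and 3 genes on the right higher in Sox2GFP+ckit+ cells (red).

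Among all named genes, 72 of 220 passed the threshold by limma with their brightest probe set, 46 higher in ckit- and 26 higher in ckit+ cells. Some of the others passed only by a dimmer probe set (limma's adjusted p from 0.027 to 0.047). Nr2e1, an orphan nuclear receptor known from neural stem cells, was higher in ckit- cells by its brighter probe set (8.31 ± 0.11 against 4.88 ± 0.35, log2, SD, n = 2, limma's adjusted p = 0.027), while its other probe set did not pass (limma's adjusted p = 0.10). Rasgrp2, an exchange factor for Rap1, was also higher in ckit- cells, with a ckit+ mean of 4.93 ± 0.09 (limma's adjusted p = 0.027). The ckit+ means of both genes lay below the highest lower quartile of the arrays (5.04), a cut chosen here without a measured detection limit. Signal and background may not be separable below it, so no fold is given. Fgd5, an exchange factor for Cdc42 known from endothelium, was 4.94-fold higher in ckit- cells, and the forkhead transcription factor Foxc2 4.72-fold (SE of the log2 difference 0.19 and 0.20). Aff3, a nuclear protein of the AF4 family, was 4.71-fold higher, with a mean of 11.30 ± 0.08 in ckit- cells. Pygl (glycogen phosphorylase) and Large2 (a glycosyltransferase) were 4.31-fold and 4.24-fold higher in ckit- cells, each with an SE of 0.16 on the log2 scale. The 10 genes that led this direction were completed by Ret, Gfra1 and Egr2, and limma's adjusted p ranged from 0.027 to 0.031.

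In the other direction, Kit led, followed by the transcription factor Runx3, 5.19-fold higher in ckit+ cells (log2 difference 2.38 ± 0.26). Its ckit- arrays had a mean of 6.95 ± 0.51 and its ckit+ arrays 9.32 ± 0.02 (log2, SD, n = 2). Met, the receptor for hepatocyte growth factor, was 4.52-fold higher in ckit+ cells by its brighter probe set (2.18 ± 0.20), while the other, 2.65-fold apart (1.40 ± 0.25), did not pass (limma's adjusted p = 0.10). Morc4 was 3.97-fold, Tc2n 3.78-fold and the muscleblind RNA-binding protein gene Mbnl3 3.62-fold higher, with SEs of 0.17, 0.21 and 0.18 on the log2 scale. The dimmer probe sets of Tc2n and Mbnl3 did not pass (limma's adjusted p = 0.099 and 0.070). Serpine2, a secreted protease inhibitor, was 3.26-fold higher (1.70 ± 0.16). Nmral1 was higher in ckit+ cells too (6.44 ± 0.35 against 4.63 ± 0.14), with a ckit- mean below the arrays' lower quartiles and so without a fold. Crabp1 and Stra8 completed these 10 genes, and limma's adjusted p ranged from 0.026 to 0.045.

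The remaining lists held few named genes, none enough for a direction test. For the cell cycle, 3 of 40 were named, all with higher values in ckit+ cells and 0 past limma's threshold over all probe sets. The log2 differences of Cdc6, a replication licensing factor, and Rrm2, a subunit of ribonucleotide reductase, were 1.33 ± 0.18 and 1.07 ± 0.16 (limma's adjusted p = 0.057 and 0.069). For the pluripotency network, 2 of 25 were named, with 0 called over all probe sets. Pou5f1, which encodes Oct4, had means of 7.64 ± 0.29 in ckit- and 6.40 ± 0.15 in ckit+ cells (log2, SD, n = 2), and Dppa2 6.55 ± 0.13 and 5.38 ± 0.04 (limma's adjusted p = 0.083 and 0.060). The only named gene of meiotic prophase was the recombinase gene Dmc1, with 8.95 ± 0.17 in ckit+ and 8.00 ± 0.00 in ckit- cells (limma's adjusted p = 0.10). For the extracellular matrix, 2 of 30 were named: Lamb1, a laminin chain, was 2.52-fold higher in ckit- cells (log2 difference 1.33 ± 0.16, limma's adjusted p = 0.043; 1 of its 3 probe sets did not pass), while Agrn (agrin) had a log2 difference of 1.20 ± 0.16 towards ckit+ cells and did not pass (limma's adjusted p = 0.057). Plvap was the only one named of 21 endothelial genes and Egr2 the only one of 27 for dissociation and stress (limma's adjusted p = 0.040 and 0.031).

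The other 14 lists had 0 named members and were not analysed here. They covered spermatids, germ cell identity and the piRNA pathway, Sertoli cells, Leydig cells, peritubular myoid cells, stromal fibroblasts, macrophages and leukocytes, mast cells, erythroid cells, Schwann cells, Notch signalling, ribosomal proteins, oxidative phosphorylation and glycolysis. This says nothing about their levels, since only probe sets selected by the authors carried a name.

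The authors' deposited table listed 374 probe sets, 196 higher in ckit- and 178 higher in ckit+ cells. Each of these 374 had the same sign in the RMA values, and the log2 differences of the authors' deposited table and of the RMA values correlated across the listed probe sets with r = 0.996 (probe sets are not independent replicates). On the RMA values 336 of the 374 in the authors' deposited table were at least 2-fold apart, and limma called 134 of them over all probe sets. Limma also called 5 probe sets outside the authors' deposited table, which carry no gene name here. Of these, 3 were higher in ckit- and 2 in ckit+ cells.

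The calls needed all 4 arrays: with any 1 of them left out limma called 0 probe sets, although 4513 to 6422 had an unadjusted p under 0.05, against 7077 with all arrays. Over all probe sets the methods' t-test called 1, while limma with an intensity trend called 419.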

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

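The tests with the methods' t-test, those adjusted over the 2-fold probe sets alone and the comparison of array splits were chosen after the results had been seen. The count of 139 calls became 554 with the replicate number as a block and 419 with an intensity trend, both including all 139 (525 and 344 at least 2-fold, against 139; 326 and 279 of the deposited table's probe sets, against 134). Same-numbered arrays deviated together with a correlation of 0.26, but the labels do not say what a number shares and there are only 2 pairs, so the block is no more than an alternative. With the block, 9 of the 10 genes taken by the naming rule that had missed limma's threshold passed it, all but Dmc1, and 7 did with the trend. The methods' t-test called 1 probe set over all probe sets (0 at least 2-fold, 0 of the deposited table's, 5346 at an unadjusted p under 0.05) and 334 when adjusted over the 2-fold probe sets alone (334 at least 2-fold, 270 of the deposited table's). Limma adjusted over the 2-fold probe sets alone called 666 of 671, of which 336 were in the deposited table. For limma this was nearly fixed by choosing probe sets on the same difference that was then tested. After such a choice neither test's adjustment can be relied on to limit false calls. The cause of the gaps between these counts was not tested beyond the number of tests adjusted for.

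With 1 array left out, the lone array is assumed to vary like the other group. Limma then called 0 probe sets in each case, 0 of them 2-fold and 0 in the deposited table, with 6422 and 5104 at an unadjusted p under 0.05 without ckit- replicate 1 or 2 and 4762 and 4513 without ckit+ replicate 1 or 2. Kit kept log2 differences of 2.78 to 2.87 but its limma adjusted p was 0.16 to 0.24, and it was 2.83 with adjusted p = 0.34 in the methods' t-test over all probe sets. Elsewhere Kit passed with adjusted p from 0.00039 to 0.028. Fewer arrays leave fewer degrees of freedom. No direction could turn among the genes taken by the naming rule, whose arrays do not overlap between populations.

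The dim filter, renewed quantile normalization and median centring gave 175, 133 and 142 calls by limma, sharing 115, 126 and 139 with the 139. The direction test of the lists uses signs alone, so most alternatives cannot change it. Both lists passed with renewed quantile normalization and median centring, and 1 passed with the dim filter: GDNF and FGF signalling then had 5 named genes, all higher in ckit- cells (Fisher's exact p = 0.059). Not run were the mean of a gene's probe sets, the choice of the brightest probe set for all genes and camera, with preset or estimated correlation, since these need names for all probe sets. The 4 arrays allow 3 splits into 2 and 2, too few for a share under 0.05: the real split gave 139 calls, the highest of the others 0, and 1 split, the real one, gave as many. At an unadjusted p under 0.05 the real split had 7077 probe sets, the split by replicate number 2177 and the crossed split 413.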

Other observations

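The tests in this part, the control probe sets and the genes outside the naming rule were chosen after the values had been seen, while Plvap, Fgd5 and Egr2 came from that rule. Other genes that passed limma's threshold with higher levels in ckit- cells were Zbtb16 (PLZF), a transcription factor of undifferentiated spermatogonia, 3.33-fold (log2 difference 1.73 ± 0.16), and Sall1, 3.46-fold (1.79 ± 0.21). Piwil4, a PIWI protein, was 3.41-fold (1.77 ± 0.17) and Cdh1 (E-cadherin) 2.46-fold higher in ckit- cells (1.30 ± 0.16). Genes that passed with higher levels in ckit+ cells were the transcription factor genes Mitf, 2.95-fold (1.56 ± 0.18), and Ebf3, 2.95-fold by its brighter probe set (1.56 ± 0.19). The dimmer Ebf3 probe set was 5.25-fold higher (2.39 ± 0.21, limma's adjusted p = 0.027). The proteoglycan gene Sdc1, 2.55-fold (1.35 ± 0.16), and the flap endonuclease gene Fen1, 2.65-fold (1.40 ± 0.16), passed in this direction too.

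In a separate limma fit over all 45101 probe sets, controls included, the control probe sets for the transferrin receptor did not pass the threshold. Their log2 differences (ckit+ minus ckit-) were 0.89 ± 0.16 at the 3′ end, 0.73 ± 0.17 in the middle and 0.79 ± 0.20 at the 5′ end, with limma's adjusted p = 0.097, 0.15 and 0.18.

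The deposited table listed 374 probe sets where limma called 139 over all probe sets. Per its header, the deposited table's p-values were adjusted over 605 tests and so not over all probe sets. A candidate explanation of the gap is that these tests were the probe sets already selected for a 2-fold difference. On the RMA values, the methods' t-test called 334 when adjusted over the 671 probe sets at least 2-fold apart and 1 when adjusted over all. The header's 605 tests are of the size of that selection. The values behind the authors' deposited table also differed from the RMA values. Of its 374 probe sets, 336 were at least 2-fold apart on the RMA values, so the rest could not have been listed from those. Whether a different normalization of the arrays made this difference, and how much of the gap it explains, stays open. With the narrower adjustment the methods' t-test on the RMA values called 270 of the 374, a share of 72.2% (exact 95% interval 67.4 to 76.7). This did not clear the bound of 70% by more than its spread, and the interval counts probe sets as independent, which they are not.

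Plvap, an endothelial gene, was 2.72-fold higher in ckit- cells. Endothelial cells in the ckit- sort are a possible explanation, although the gate on the Sox2 reporter would remove cells that lack it. Only 1 of the 21 listed endothelial genes was named, and that 1 was higher in ckit- cells, so the test had too few genes. The others were not among the named probe sets that the authors had listed. Listed probe sets were at least 2-fold apart with adjusted p-values up to 0.05 in the authors' t-test. An unlisted gene could therefore differ by 2-fold and have missed that threshold. However, 118 of the selected probe sets stayed unnamed, and the levels of the abundant endothelial transcripts were not analysed here. Some named genes outside the endothelial list are known from endothelium. Of these, Fgd5 and Arhgef15 were higher in ckit- cells, and Fli1 had a higher value there without passing limma's threshold. Ephb4, Unc5b and Efnb2 had higher values in ckit+ cells without passing it. Both Fli1 means (4.97 and 3.77) and the ckit- mean of Efnb2 (4.41) lay below 5.04, where signal and background may not be separable. These genes were picked by hand, not from a fixed list and not completely, so the number on each side carries no weight. Expression of Plvap by other Sox2GFP+ckit- cells, not endothelial ones, stays open as well and was not tested.

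Egr2, an immediate early gene, was 4.58-fold higher in ckit- cells. A stress response to dissociation could raise it, and so could GDNF signalling, of which Egr2 is a known target in spermatogonia and which was not tested as a cause. Of the 27 listed dissociation genes 1 was named, Egr2 itself, higher in ckit- cells, so this test cannot separate the explanations. The others were not among the named probe sets that passed the authors' 2-fold rule and t-test. However, 118 selected probe sets stayed unnamed. Both populations went through the same dissociation according to the labels.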
